A study of Homo sapiens with 9 samples.

How the data were processed

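RNA was measured in 9 libraries of IMR90 cells, a widely used strain of human fetal lung fibroblasts. Per the labels' protocols, cells were given lentiviral particles carrying a short hairpin RNA (shRNA, which directs degradation of a matching mRNA) against COL6A3, or particles carrying a control shRNA, at a multiplicity of infection of 1, with puromycin used for selection and culture at 20% oxygen. The third group is labelled only as control. Its titles spell the cells IMR9, while the descriptions of its libraries read IMR90, which is used here. A label text gives control cells particles with a control shRNA, so whether and how the cells of this group were transduced or selected is not given in the sources used here. Each group had 3 libraries. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. RNA was column purified with DNase digestion, polyadenylated RNA was taken for a strand-preserving library kit, and libraries were sequenced as 100 nt paired-end reads, per the labels' protocols.

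The authors deposited 1 table of raw read counts per gene, with 58884 Ensembl gene identifiers and the 9 libraries. STAR 2.7.3a, featureCounts, limma, R 3.0.3 and genome build GRCh38 are named in the submitters' processing notes. The annotation release, the strand setting of the counting and the treatment of reads that match several places are not given in the sources used here. Reads of near-identical genes can therefore be dropped or split, which touches histone, HLA, metallothionein, ribosomal protein and AKR1C genes and named pseudogenes, and levels of these are uncertain. Reads of overlapping genes are uncertain for the same reason. Without molecular identifiers, amplification copies of a fragment are counted as separate reads, so floors and intervals built from counts cover counting error only. Columns were matched to libraries by the number in each library's description. Symbols came from a table of gene names, which matched 58472 identifiers (99.3%), and otherwise from GENCODE 29 on GRCh38, which also gave the coordinates.

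Library totals lay between 26659173 and 33551377 counts. Genes were kept with the edgeR function filterByExpr by group (minimum count 10, minimum total 15), which left 16642 genes. All 31097 genes with no count in any library were among those left out. Libraries were scaled by TMM (factors 0.993 to 1.014), and levels are CPM from the edgeR function cpm with these factors. Log2 CPM values used a prior count of 2. The edgeR quasi-likelihood F-test (edgeR 4.0.16 in R 4.3.3) was fitted once over all 9 libraries with a mean per group, which leaves 6 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method over the 16642 genes. A gene is called changed at an adjusted p below 0.05. Standard errors were taken as the log2 fold change divided by the square root of F. Intervals for COL6A3, COL6A1 and COL6A2 have a level of 95%, from the t distribution with the residual and the median prior degrees of freedom.

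A set of 37 gene lists was fixed before the data were examined, covering collagens and other matrix, proteases, receptors, secreted factors of senescent cells, cell cycle, chromatin, stress responses, metabolism, fibroblast identity and markers of other cell types. COL6A3 itself is in none of them. Lists with at least 5 tested members, 32 in number, were tested with camera of limma 3.58.1 on the same fit, which asks whether members rank higher or lower than other genes, with a preset correlation between genes of 0.01 and adjustment over the lists. The same test with a correlation estimated per list and fry, which tests members alone, were alternatives. The preset test also called lists in splits of the libraries that mix the groups, so its p-values may be too small. Members of a list are counted by the adjustment over all genes and also adjusted over the list alone.

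The genes named were set by a rule before the data were examined. It takes COL6A3, COL6A1 and COL6A2, then per comparison the 8 largest rises and the 8 largest falls among called genes with a symbol, a mean log2 CPM of at least 2 and no overlap between the libraries of both groups. From each list it takes up to 3 called members with the smallest adjusted p, or the most abundant tested member where none was called. Genes outside the rule are marked as chosen after their values were seen.

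The 3 comparisons share libraries in pairs, so overlaps between their calls were set against 20 simulated data sets of unchanged groups with the dispersions of each group, and against the product of the call rates. The pipeline was tested on simulated counts with 200 changed genes in each of 5 draws. A further small set of genes, raised by less, was left out of the count of false calls. All groups were given the same dispersion per gene, whereas the control shRNA libraries varied more in the data. The rates that follow may therefore not hold for comparisons with that group. For COL6A3 shRNA against control shRNA, 36.2% of genes changed 1.5-fold and 59.6% of those changed 2-fold were called over 16597 genes, with 3.84% false calls. For COL6A3 shRNA against control the values were 36.8%, 60.0% and 3.28% over 16597 genes. No gene was called in the simulated comparison without a change.

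Alternatives fixed before the data were examined were size factors of DESeq2, upper-quartile factors, no filter or a filter of 50 counts in 3 libraries, the DESeq2 Wald test (DESeq2 1.42.0), limma voom, a replicate block, a fit of only the groups compared, each library left out, an adjusted p below 0.01, and glmTreat at 1.5-fold. Added after the data were seen were limma voom with library quality weights and a fit without control shRNA replicates 2 and 3. The senescent samples and other cell types named in the series' design text were not analysed here.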

Results

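Polyadenylated RNA was profiled in IMR90 human fetal lung fibroblasts in 3 groups of 3 libraries. The groups were cells given a COL6A3 shRNA, cells given a control shRNA, and cells labelled only as control. COL6A3 encodes a chain of collagen VI, which forms microfibrils in the matrix around cells, and the series as a whole deals with cellular senescence. The libraries held 26659173 to 33551377 counts. A count was present for 19384 to 20392 genes in 7 libraries, and for 17613 and 18364 genes in control shRNA replicates 2 and 3. Values given for a gene are log2 fold changes with their standard error (SE) from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, with n = 3 per group. Medians of lists are medians of the log2 fold changes of the tested members.

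The target was low in each library with the COL6A3 shRNA. COL6A3 (ENSG00000163359, chromosome 2, 237324003 to 237414375, minus strand, GRCh38) fell from 8355 ± 517 CPM to 2427 ± 12.8 CPM (mean ± SD, n = 3) relative to control shRNA. This is a log2 fold change of -1.78 (SE 0.046, adjusted p = 1.8e-19), or 29.0% of the control shRNA level (95% interval 27.2 to 31.0%). The group labelled control stood at 5924 ± 307 CPM. Against it the log2 fold change was -1.29 (SE 0.045, adjusted p = 1.7e-16), or 41.0% (95% interval 38.4 to 43.7%). The groups did not overlap, at 2412 to 2435 CPM with the COL6A3 shRNA, 5592 to 6197 CPM in control and 7762 to 8708 CPM with the control shRNA. COL6A3 was itself higher with the control shRNA than in control, by 0.50 (SE 0.045, adjusted p = 1.5e-08). Its partner chains are COL6A1 (ENSG00000142156, chromosome 21, 45981737 to 46005050) and COL6A2 (ENSG00000142173, chromosome 21, 46098097 to 46132849). Both fell against control shRNA, with COL6A1 at -0.57 (SE 0.065) and COL6A2 at -0.46 (SE 0.072) and adjusted p of at most 8.5e-05. Against control neither passed the test. COL6A1 stood at 0.063 (95% interval -0.070 to 0.20, adjusted p = 0.768) and COL6A2 at 0.12 (95% interval -0.029 to 0.27, adjusted p = 0.497).

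**Figure D1:**
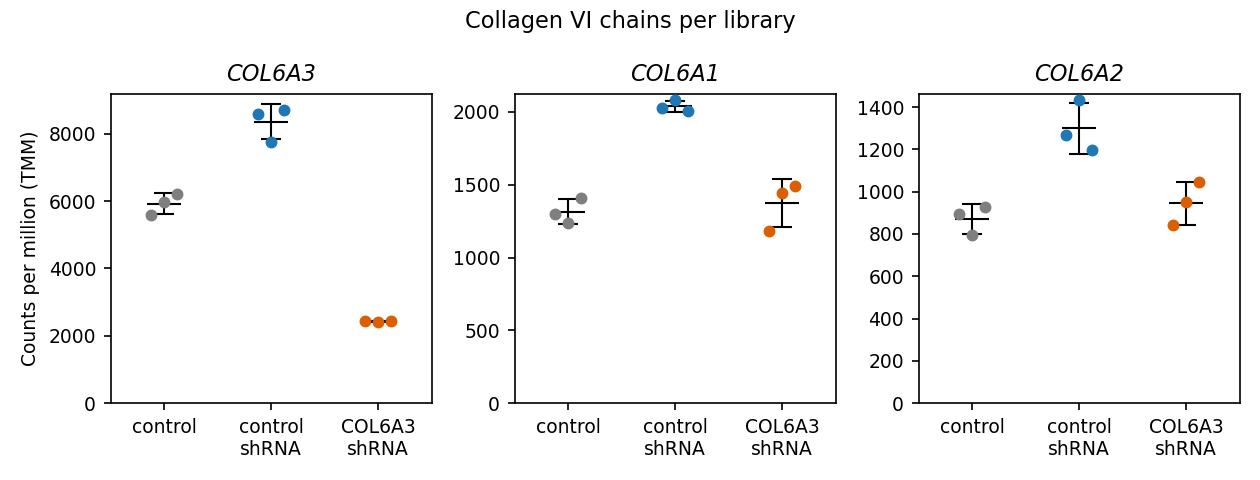
TMM-scaled CPM of COL6A3, COL6A1 and COL6A2 in each library of the 3 groups, with points for libraries and bars for the mean ± SD (n = 3). COL6A3 averaged 2427 CPM with its shRNA, 8355 CPM with the control shRNA and 5924 CPM in control.

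The comparison of COL6A3 shRNA with control shRNA asks what lowering COL6A3 changes relative to cells given particles with a control hairpin. Cells with the COL6A3 shRNA had lower levels of mitotic genes, unfolded protein response genes, amino acid genes under ATF4, immediate early genes, and a mixed list of matrix proteases and inhibitors. They had higher levels of genes of sterol synthesis and uptake. Of 16642 genes tested, 1920 changed, 1118 up and 802 down, of which 98 and 110 changed at least 2-fold. Large rises were those of NPR3, a natriuretic peptide receptor, FAT3, an atypical cadherin, ITGB8, an integrin subunit, and PCDH10, a protocadherin. Values were 1.70 (SE 0.11) for NPR3, 1.68 (SE 0.17) for FAT3, 1.55 (SE 0.13) for ITGB8 and 1.56 (SE 0.25) for PCDH10, with adjusted p of at most 8.7e-05. Large falls were those of HSD17B2, a steroid dehydrogenase, TMEM176B, a membrane protein, and FGL2, a fibrinogen-like protein. Values were -2.19 (SE 0.24) for HSD17B2, -2.24 (SE 0.22) for TMEM176B and -1.78 (SE 0.16) for FGL2, with adjusted p of at most 4.3e-07. Libraries of both groups did not overlap for 4414 genes (26.5%, where chance gives 10%). The number of changed genes was 1203 without COL6A3 shRNA replicate 1, and 1270 without control shRNA replicates 2 and 3, the libraries with the fewest genes detected.

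Cell division genes had the lowest median of the lists tested. Among G2/M and mitotic genes, 29 of 46 tested members fell and 17 did not pass (37 fell when adjusted over the list alone). The median was -1.16, with a camera adjusted p of 1.3e-27. Examples are CDC20, which activates the anaphase-promoting complex, BIRC5, which encodes survivin, MKI67, the proliferation marker Ki-67, and TOP2A, a DNA topoisomerase. Values were -2.34 (SE 0.27) for CDC20, -1.99 (SE 0.25) for BIRC5, -1.63 (SE 0.15) for MKI67 and -1.39 (SE 0.13) for TOP2A, with adjusted p of at most 3.4e-06. MKI67 went from 32.6 ± 2.59 CPM to 10.5 ± 1.87 CPM (mean ± SD, n = 3). Among DNA replication and E2F target genes, 8 of 43 tested members fell and 35 did not pass (11 fell when adjusted over the list alone). The median was -0.42, with a camera adjusted p of 7.3e-07. RRM2, a subunit of ribonucleotide reductase, and UHRF1, a factor of DNA methylation maintenance, stood at -1.74 (SE 0.20) and -0.78 (SE 0.18). Among lamina and chromatin genes known to decline in senescent cells, 9 of 15 tested members fell and 6 did not pass (9 fell when adjusted over the list alone). The median was -0.36, with a camera adjusted p of 9.1e-07. LMNB1, which encodes lamin B1, stood at -1.26 (SE 0.26) and HMGB1, a chromatin protein, at -0.50 (SE 0.075).

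Among p53 targets and cyclin-dependent kinase inhibitors, 8 of 27 tested members rose, 1 fell and 18 did not pass (8 rose and 2 fell when adjusted over the list alone). The median was 0.089, with a camera adjusted p of 0.00069. CCNG1, a cyclin induced by p53, CDKN2B, a kinase inhibitor, and RRM2B, a p53-induced ribonucleotide reductase subunit, stood at 0.80 (SE 0.075), 0.63 (SE 0.091) and 0.59 (SE 0.084). CDKN1A and CDKN2A, kinase inhibitors often read in senescence, lie outside the naming rule and were chosen after their values were seen. Neither passed, with CDKN1A at 0.074 (SE 0.053, adjusted p = 0.462) and CDKN2A at 0.070 (SE 0.17, adjusted p = 0.873). Among secreted factors of senescent cells, 5 of 31 tested members rose, 4 fell and 22 did not pass (5 rose and 6 fell when adjusted over the list alone). This list was not called (camera adjusted p = 0.521). INHBA, an activin subunit, TNFRSF11B, a decoy receptor also called osteoprotegerin, and IGFBP5 stood at 0.80 (SE 0.073), -0.76 (SE 0.063) and -0.53 (SE 0.033). Among histone genes, 6 of 7 tested members rose and 1 did not pass (6 rose when adjusted over the list alone). The median was 0.79, with a camera adjusted p of 4.7e-06. These are levels of polyadenylated RNA only, so histone mRNA without a poly(A) tail was not measured. The levels are also uncertain because of near-identical copies.

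The unfolded protein response, ATF4 amino acid and immediate early lists ranked lower against control shRNA. In the unfolded protein response list, 17 of 27 tested members fell, 0 rose and 10 did not pass (19 fell and 2 rose when adjusted over the list alone). The median was -0.42, with a camera adjusted p of 5.8e-22. The chaperone genes CALR, HSPA5 and HSP90B1 stood at -0.83 (SE 0.056), -0.68 (SE 0.059) and -0.64 (SE 0.058), and CALR went from 1063 ± 32.5 CPM to 597 ± 41.0 CPM (mean ± SD, n = 3). In the list of amino acid genes under ATF4, 17 of 24 tested members fell, 2 rose and 5 did not pass (17 fell and 3 rose when adjusted over the list alone). The median was -0.36, with a camera adjusted p of 5.7e-15. The tRNA synthetase gene WARS1 and the serine synthesis genes PHGDH and PSAT1 stood at -0.71 (SE 0.064), -0.68 (SE 0.069) and -0.56 (SE 0.064). Among immediate early genes, 13 of 26 tested members fell and 13 did not pass (15 fell when adjusted over the list alone). The median was -0.50, with a camera adjusted p of 5.2e-13. The transcription factor genes FOSB and EGR1 stood at -1.66 (SE 0.18) and -0.87 (SE 0.096). Sterol genes moved the other way. In the cholesterol synthesis list, 22 of 28 tested members rose and 6 did not pass (24 rose when adjusted over the list alone). The median was 0.38, with a camera adjusted p of 2.6e-27. STARD4, a sterol carrier, and SCD, a fatty acid desaturase, stood at 0.89 (SE 0.079) and 0.47 (SE 0.045).

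Matrix genes changed in both directions. Among matrix proteases and their inhibitors, 11 of 24 tested members fell, 1 rose and 12 did not pass (12 fell and 2 rose when adjusted over the list alone). The median was -0.28, with a camera adjusted p of 9.6e-10. PLAU, which encodes urokinase, and the protease inhibitor genes SERPINE2 and TIMP1 stood at -0.92 (SE 0.068), -0.90 (SE 0.082) and -0.61 (SE 0.054). Among collagens other than type VI, 10 of 21 tested members fell, 3 rose and 8 did not pass (11 fell and 3 rose when adjusted over the list alone). The median was -0.18, with a camera adjusted p of 0.0244, and adjusted p = 0.242 with an estimated correlation. The call was also lost without control shRNA replicate 3 (adjusted p = 0.0893). COL11A1, a minor fibrillar collagen, rose, and COL15A1 and COL3A1 fell, with COL11A1 at 1.49 (SE 0.074), COL15A1 at -1.19 (SE 0.095) and COL3A1 at -0.52 (SE 0.046). In collagen processing, 7 of 22 tested members fell, 1 rose and 14 did not pass (7 fell and 1 rose when adjusted over the list alone). The median was -0.095, with a camera adjusted p of 0.00024, and adjusted p = 0.182 with an estimated correlation. The collagen chaperone gene SERPINH1 stood at -0.54 (SE 0.059). Among matrix glycoproteins and proteoglycans, 9 of 40 tested members fell, 7 rose and 24 did not pass (11 fell and 10 rose when adjusted over the list alone). This list was not called (camera adjusted p = 0.536, ranked lower, while its median was 0.019). For matrix receptors, 6 of 26 tested members fell, 5 rose and 15 did not pass (8 fell and 6 rose when adjusted over the list alone), and the list was not called (camera adjusted p = 0.635).

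Further lists were called here with the preset correlation only. Among hypoxia and glycolysis genes, 11 of 27 tested members rose and 16 did not pass (14 rose when adjusted over the list alone), with adjusted p = 0.138 with an estimated correlation. PDK1, a kinase that inhibits pyruvate dehydrogenase, and NDRG1, a hypoxia-induced gene, stood at 0.86 (SE 0.11) and 0.64 (SE 0.080). Among NRF2 and antioxidant genes, 7 of 24 tested members rose, 1 fell and 16 did not pass (11 rose and 2 fell when adjusted over the list alone), with adjusted p = 0.182 with an estimated correlation. Lists that ranked lower were mitochondrially encoded mRNAs, ribosomal proteins, MHC class I genes, lung fibroblast markers and endothelial markers. Their adjusted p with an estimated correlation was 0.356, 0.548, 0.182, 0.0508 and 0.213. Among fibroblast markers, 5 of 20 tested members fell, 2 rose and 13 did not pass (7 fell and 4 rose when adjusted over the list alone), and among mitochondrially encoded mRNAs, 5 of 13 tested members fell and 8 did not pass (7 fell when adjusted over the list alone). For ribosomal proteins, 6 of 44 tested members fell, 1 rose and 37 did not pass (9 fell and 1 rose when adjusted over the list alone), and the call was lost without control shRNA replicate 2 (adjusted p = 0.120). For MHC class I, 2 of 15 tested members fell and 13 did not pass (2 fell when adjusted over the list alone), and the call was lost without control shRNA replicate 1 (adjusted p = 0.0792), COL6A3 shRNA replicate 2 (adjusted p = 0.0606) or COL6A3 shRNA replicate 3 (adjusted p = 0.0552). In total 19 of 32 lists were called, 5 higher and 14 lower. With an estimated correlation 10 held, with adjusted p of at most 0.0471: G2/M, DNA replication, lamina, immediate early, unfolded protein response, ATF4, proteases, cholesterol, p53 and histone genes.

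**Figure D2:**
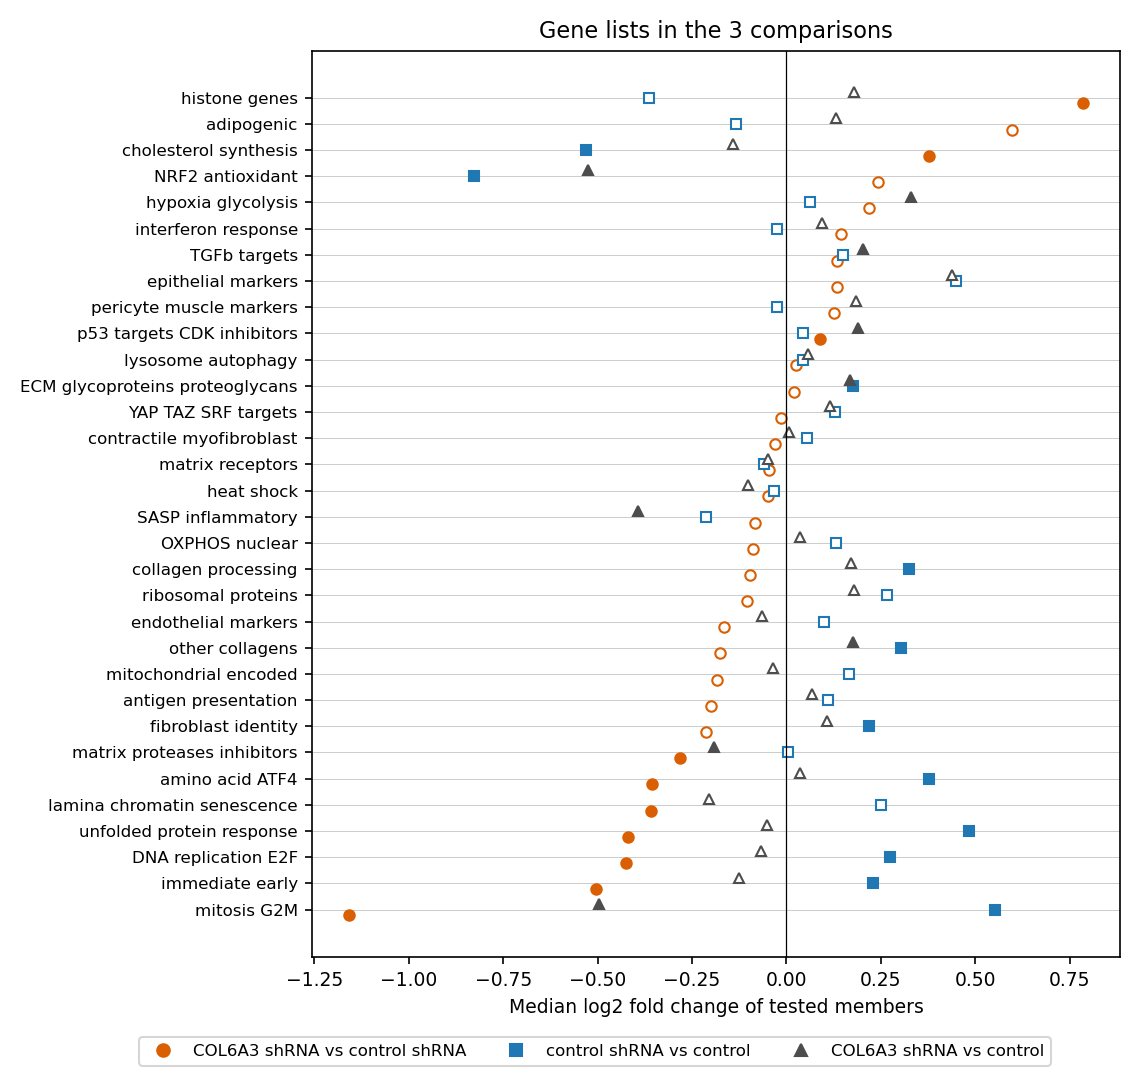
Median log2 fold change of the tested members (x axis) of 32 gene lists (y axis) in the 3 comparisons, with a colour and symbol for each comparison. Filled symbols are lists called by camera with both the preset and an estimated correlation, and G2/M genes lie at -1.16, 0.55 and -0.50.

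The comparison of control shRNA with the group labelled control sets cells given control particles against cells for which no shRNA is named. Cells with the control shRNA had higher levels of collagens, other matrix genes, unfolded protein response genes, amino acid genes under ATF4 and mitotic genes. They had lower levels of NRF2 and antioxidant genes and of genes of sterol synthesis and uptake. In total 2290 of 16642 genes changed, 940 up and 1350 down, of which 83 and 125 changed at least 2-fold. Large rises were those of WNT2, a secreted Wnt ligand, CCN4, a matricellular protein, and POSTN, which encodes periostin. Values were 2.17 (SE 0.30) for WNT2, 1.46 (SE 0.15) for CCN4 and 1.35 (SE 0.081) for POSTN, with adjusted p of at most 1.2e-05. Large falls were those of TMEM178B, a membrane protein, SYNPO2, an actin-associated protein, and A2M, a protease inhibitor, with TMEM178B at -2.18 (SE 0.17), SYNPO2 at -1.95 (SE 0.13) and A2M at -2.05 (SE 0.29). AL355075.4 had 0 counts in all 3 control libraries and 2155 to 4048 counts in the 6 shRNA libraries. Libraries of both groups did not overlap for 4680 genes (28.1%, where chance gives 10%). Of markers of other cell types, 2 of 6 endothelial, 1 of 3 mesothelial and neural and 1 of 4 keratinocyte and melanocyte markers fell. Of 8 pericyte and muscle markers, 1 rose and 1 fell. Adjusted over each list alone these counts were the same, apart from 1 mesothelial and neural marker that rose.

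Collagen genes rose with the control shRNA. Among collagens other than type VI, 13 of 21 tested members rose, 2 fell and 6 did not pass (15 rose and 2 fell when adjusted over the list alone). The median was 0.30, with a camera adjusted p of 7.9e-13. COL1A1, COL3A1 and COL5A1, chains of fibrillar collagens, stood at 0.75 (SE 0.043), 0.70 (SE 0.046) and 0.80 (SE 0.054), and COL1A1 went from 9561 ± 589.8 CPM to 16088 ± 645 CPM (mean ± SD, n = 3). COL6A1 and COL6A2 rose too, with COL6A1 at 0.63 (SE 0.065) and COL6A2 at 0.58 (SE 0.072). Among matrix glycoproteins and proteoglycans, 18 of 40 tested members rose, 4 fell and 18 did not pass (19 rose and 5 fell when adjusted over the list alone). The median was 0.18, with a camera adjusted p of 1.5e-08. SPARC, a collagen-binding protein, stood at 0.63 (SE 0.043). In collagen processing, 15 of 22 tested members rose, 1 fell and 6 did not pass (16 rose and 2 fell when adjusted over the list alone). The median was 0.33, with a camera adjusted p of 2.8e-12. The collagen chaperone SERPINH1 and the crosslinking enzyme LOXL2 stood at 0.65 (SE 0.059) and 0.45 (SE 0.056). Among lung fibroblast markers, 5 of 20 tested members rose, 1 fell and 14 did not pass (7 rose and 2 fell when adjusted over the list alone). The median was 0.22, with a camera adjusted p of 0.00622. For proteases and inhibitors, 6 of 24 tested members rose, 5 fell and 13 did not pass (8 rose and 8 fell when adjusted over the list alone), and the list was not called (camera adjusted p = 0.542). The genes of the metalloproteinases gelatinase A (MMP2), stromelysin (MMP3) and interstitial collagenase (MMP1) stood at 0.61 (SE 0.048), -1.22 (SE 0.13) and -0.69 (SE 0.081).

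Several lists moved opposite to their direction between the shRNA groups. In the unfolded protein response list, 16 of 27 tested members rose, 2 fell and 9 did not pass (18 rose and 3 fell when adjusted over the list alone). The median was 0.48, with a camera adjusted p of 1.5e-15. CALR, HSPA5 and HSP90B1 stood at 0.88 (SE 0.056), 0.78 (SE 0.059) and 0.52 (SE 0.057). In the ATF4 list, 15 of 24 tested members rose, 2 fell and 7 did not pass (17 rose and 2 fell when adjusted over the list alone). The median was 0.38, with a camera adjusted p of 6.2e-13. PHGDH and PSAT1 rose and SLC7A11, a cystine transporter, fell, with PHGDH at 0.88 (SE 0.070), PSAT1 at 0.64 (SE 0.064) and SLC7A11 at -1.19 (SE 0.079). Among G2/M genes, 14 of 46 tested members rose and 32 did not pass (19 rose when adjusted over the list alone). The median was 0.55, with a camera adjusted p of 9.6e-09. MKI67 and TOP2A stood at 0.95 (SE 0.15) and 0.79 (SE 0.13). Among DNA replication genes, 6 of 43 tested members rose and 37 did not pass (6 rose when adjusted over the list alone). The median was 0.28, with a camera adjusted p of 0.00047. Among immediate early genes, 7 of 26 tested members rose, 1 fell and 18 did not pass (10 rose and 1 fell when adjusted over the list alone). The median was 0.23, with a camera adjusted p of 6.3e-06. In cholesterol synthesis, 22 of 28 tested members fell and 6 did not pass (23 fell when adjusted over the list alone). The median was -0.53, with a camera adjusted p of 5.8e-43. The pathway enzyme genes IDI1 and HMGCS1 stood at -1.08 (SE 0.068) and -1.01 (SE 0.064).

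NRF2 and antioxidant genes had the lowest median of the lists tested in this comparison. In that list, 19 of 24 tested members fell and 5 did not pass (20 fell when adjusted over the list alone). The median was -0.83, with a camera adjusted p of 4.5e-43. GCLM, a subunit of the enzyme that starts glutathione synthesis, SOD2, the mitochondrial superoxide dismutase, and TXNRD1, thioredoxin reductase, stood at -1.65 (SE 0.12), -1.46 (SE 0.087) and -1.10 (SE 0.054). TXNRD1 went from 2264 ± 43.2 CPM to 1055 ± 36.4 CPM (mean ± SD, n = 3). Among secreted factors of senescent cells, 10 of 31 tested members fell, 3 rose and 18 did not pass (10 fell and 4 rose when adjusted over the list alone). The median was -0.21, with a camera adjusted p of 0.0170, and adjusted p = 0.159 with an estimated correlation. The call was lost without control shRNA replicate 2 (adjusted p = 0.0799). The growth factor genes NRG1 and FGF2 and the chemokine gene CCL2 stood at -1.09 (SE 0.13), -0.76 (SE 0.076) and -0.93 (SE 0.090). Among ribosomal proteins, 38 of 44 tested members rose, 0 fell and 6 did not pass (40 rose and 1 fell when adjusted over the list alone). The median was 0.27, with a camera adjusted p of 3.4e-20, and adjusted p = 0.159 with an estimated correlation. In total 18 of 32 lists were called, 14 higher and 4 lower, and 11 held with an estimated correlation, with adjusted p of at most 0.0480. The calls of the lamina, MHC class I, mitochondrially encoded, nuclear respiratory chain and histone lists were lost. Their adjusted p was 0.167, 0.144, 0.584, 0.584 and 0.159 with an estimated correlation. Leaving out 1 library ended the calls of the mitochondrially encoded list without control shRNA replicate 1 (adjusted p = 0.0855) or control replicate 3 (adjusted p = 0.0678), of the respiratory chain list without control shRNA replicate 2 (adjusted p = 0.345) or control replicate 2 (adjusted p = 0.0958), and of the histone list without control shRNA replicate 3 (adjusted p = 0.0620). Without both control shRNA replicates 2 and 3, the calls of the secreted factor, lamina and respiratory chain lists were lost (adjusted p = 0.126, 0.0713 and 0.331).

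The comparison of COL6A3 shRNA with the group labelled control sets the knockdown against cells for which no shRNA is named. Cells with the COL6A3 shRNA had higher levels of hypoxia and glycolysis genes, matrix genes and TGF-beta targets. They had lower levels of NRF2 and antioxidant genes, of the mixed list of matrix proteases and inhibitors, and of mitotic genes. The collagen, matrix glycoprotein and NRF2 lists moved the same way with the control shRNA, with medians of 0.30, 0.18 and -0.83. Their changes against control are therefore not particular to the COL6A3 shRNA. In total 804 of 16642 genes changed, 386 up and 418 down, of which 54 and 48 changed at least 2-fold. Of the 804 genes, 402 were called in the same direction for control shRNA against control, 166 higher and 236 lower. The product of the call rates gives 21.8 and 33.9. Both comparisons share the control libraries, which may give part of that overlap. TRPA1, an ion channel that senses irritants, went from 303 ± 20.7 CPM to 79.6 ± 9.91 CPM (mean ± SD, n = 3), a change of -1.93 (SE 0.081, adjusted p = 7.8e-15). HSD17B2 and FGL2 stood at -3.59 (SE 0.24) and -2.34 (SE 0.16). Large rises were those of COL11A1, APOE, which encodes apolipoprotein E, and PCDH10, with COL11A1 at 1.71 (SE 0.075), APOE at 1.69 (SE 0.28) and PCDH10 at 1.64 (SE 0.25) and adjusted p of at most 0.00028. Libraries of both groups did not overlap for 3830 genes (23.0%, where chance gives 10%). Of markers of other cell types, 1 of 6 endothelial and 1 of 3 mesothelial and neural markers fell, and 1 of 8 pericyte and muscle markers rose, with the same counts adjusted over each list alone. The number of changed genes was 522 without COL6A3 shRNA replicate 2, 517 without COL6A3 shRNA replicate 3 and 522 without control replicate 3.

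Hypoxia and glycolysis genes rose against control. In that list, 15 of 27 tested members rose, 2 fell and 10 did not pass (16 rose and 2 fell when adjusted over the list alone). The median was 0.33, with a camera adjusted p of 2.5e-14. NDRG1, BNIP3, a mitophagy receptor, and LDHA, lactate dehydrogenase, stood at 0.76 (SE 0.080), 0.74 (SE 0.089) and 0.63 (SE 0.077). Among TGF-beta targets, 5 of 24 tested members rose, 2 fell and 17 did not pass (6 rose and 2 fell when adjusted over the list alone). The median was 0.20, with a camera adjusted p of 4.0e-06. INHBA, LRRC15 and TGFBI stood at 0.91 (SE 0.073), 0.99 (SE 0.15) and 0.57 (SE 0.054). Among matrix glycoproteins and proteoglycans, 11 of 40 tested members rose, 4 fell and 25 did not pass (18 rose and 5 fell when adjusted over the list alone). The median was 0.17, with a camera adjusted p of 2.8e-10. POSTN, THBS2, a thrombospondin, and LAMA4, a laminin chain, stood at 1.38 (SE 0.081), 1.02 (SE 0.071) and 0.73 (SE 0.067). Among collagens other than type VI, 9 of 21 tested members rose, 2 fell and 10 did not pass (10 rose and 2 fell when adjusted over the list alone). The median was 0.18, with a camera adjusted p of 9.2e-10. COL1A1 and COL1A2 stood at 0.48 (SE 0.043) and 0.33 (SE 0.035). Among p53 targets and kinase inhibitors, 5 of 27 tested members rose, 0 fell and 22 did not pass (6 rose and 1 fell when adjusted over the list alone). The median was 0.19, with a camera adjusted p of 0.00012. CCNG1 and GDF15, a stress-induced cytokine, stood at 0.39 (SE 0.075) and 0.53 (SE 0.12).

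Other lists fell against control. In the NRF2 and antioxidant list, 14 of 24 tested members fell and 10 did not pass (16 fell when adjusted over the list alone). The median was -0.53, with a camera adjusted p of 3.3e-37. GCLM, SOD2 and TXNRD1 stood at -1.31 (SE 0.12), -0.91 (SE 0.085) and -0.82 (SE 0.053). Among proteases and inhibitors, 11 of 24 tested members fell, 2 rose and 11 did not pass (12 fell and 2 rose when adjusted over the list alone). The median was -0.19, with a camera adjusted p of 9.2e-10. SERPINE2, TIMP1 and ADAMTS1, a metalloprotease, stood at -0.89 (SE 0.082), -0.78 (SE 0.055) and -0.52 (SE 0.051). Among secreted factors of senescent cells, 8 of 31 tested members fell, 6 rose and 17 did not pass (14 fell and 6 rose when adjusted over the list alone). The median was -0.39, with a camera adjusted p of 8.5e-05. TNFRSF11B and IGFBP5 fell and INHBA rose, with TNFRSF11B at -1.14 (SE 0.063), IGFBP5 at -0.52 (SE 0.033) and INHBA at 0.91 (SE 0.073). Among G2/M genes, 6 of 46 tested members fell and 40 did not pass (11 fell when adjusted over the list alone). The median was -0.50, with a camera adjusted p of 2.6e-08. CDC20, MKI67 and TOP2A stood at -1.23 (SE 0.27), -0.68 (SE 0.15) and -0.61 (SE 0.13). TOP2A lost its call without control replicate 2 (adjusted p = 0.0532), and CDC20 with limma voom (adjusted p = 0.0586).

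The unfolded protein response and ATF4 lists, which fell against control shRNA, were not called against control. In the unfolded protein response list edgeR called 0 of 27 tested members (0 rose and 0 fell when adjusted over the list alone), with 6 at an unadjusted p below 0.05, 2 called by DESeq2 and 1 by limma voom. The median was -0.051, with a camera adjusted p of 0.327, and without COL6A3 shRNA replicate 3 the list was called lower (adjusted p = 0.0319). In the ATF4 list, 1 of 24 tested members rose, 1 fell and 22 did not pass (5 rose and 3 fell when adjusted over the list alone). It ranked lower (camera adjusted p = 0.939), while its median was 0.036. In cholesterol synthesis, 8 of 28 tested members fell, 1 rose and 19 did not pass (11 fell and 1 rose when adjusted over the list alone). The median was -0.14, with a camera adjusted p of 1.3e-05, and adjusted p = 0.155 with an estimated correlation. In total 17 of 32 lists were called, 8 higher and 9 lower, and 9 held with an estimated correlation, with adjusted p of at most 0.0442. Collagen processing, ribosomal protein and lysosome genes ranked higher, with adjusted p = 0.154, 0.212 and 0.212 with an estimated correlation. The lamina, immediate early, heat shock and endothelial lists ranked lower, with adjusted p = 0.253, 0.119, 0.172 and 0.0666 with an estimated correlation. The immediate early list was not called without control replicate 2 (adjusted p = 0.128), nor the heat shock list without COL6A3 shRNA replicate 2 (adjusted p = 0.05002) or control replicate 1 (adjusted p = 0.103). The lamina list was not called without COL6A3 shRNA replicate 3 (adjusted p = 0.128), control replicate 2 (adjusted p = 0.0635) or control replicate 3 (adjusted p = 0.0944), nor the lysosome list without COL6A3 shRNA replicate 1 (adjusted p = 0.0524), control replicate 2 (adjusted p = 0.0697) or control replicate 3 (adjusted p = 0.0900). Without COL6A3 shRNA replicate 3, mitochondrially encoded mRNAs were called lower (adjusted p = 0.00224), and histone genes and pericyte markers higher (adjusted p = 0.0281 and 0.0474). Epithelial markers were called higher without COL6A3 shRNA replicate 1 (adjusted p = 0.0415), and YAP and SRF targets without COL6A3 shRNA replicate 2 (adjusted p = 0.0341).

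Genes called the same way against both controls numbered 291, 151 up and 140 down, or 15.2% of the 1920 called against control shRNA. A further 69 genes were called against both controls in opposite directions. With the log2 fold change against control shRNA given first and that against control second, rises included COL11A1 (1.49 and 1.71), ITGB8 (1.55 and 1.47), PCDH10 (1.56 and 1.64) and INHBA (0.80 and 0.91). Falls included TRPA1 (-1.66 and -1.93), HSD17B2 (-2.19 and -3.59), FGL2 (-1.78 and -2.34) and TNFRSF11B (-0.76 and -1.14). Of 27 hypoxia and glycolysis genes, 9 rose against both, among them PDK1, NDRG1 and BNIP3. Of 24 proteases and inhibitors, 7 fell against both, among them PLAU, SERPINE2 and TIMP1. Of 46 G2/M genes, 6 fell against both, among them CDC20, MKI67 and TOP2A. The product of the call rates gives 25.9 rises and 20.1 falls, but leaves out the sharing of libraries. The mean overlap was 0 in 20 simulated data sets without any effect, which is no measure of that sharing because such sets give next to no calls. Part of any excess may come from the shared knockdown libraries, which are too few to divide. The covariance of both sets of log2 fold changes over all 16642 genes was 0.16, against 0.13 simulated, so most of that covariance arises without any effect. Each gene counts equally in it, so it does not tell how many of the 291 overlapping calls do.

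Calls against control shRNA also had counterparts between the control groups. That comparison called 13.8% of all genes, and COL6A3 shRNA against control called 4.83%. A larger overlap follows from these rates alone, so the sizes of both overlaps are not compared. Of the 1920 genes, 1070 (55.7%) were called in the opposite direction between control shRNA and control, 713 of them higher and 357 lower with the COL6A3 shRNA. The product of the call rates gives 90.7 and 45.3, again without the sharing of libraries, and the simulated mean overlap of 0 has the same limit. Part of any excess may come from the shared control shRNA libraries. Both sets shared 39 genes, and 598 genes (31.1%) were in neither. CALR stood at 1063 ± 32.5 CPM with the control shRNA, 597 ± 41.0 CPM with the COL6A3 shRNA and 577 ± 8.62 CPM in control. The covariance of both sets of log2 fold changes over all 16642 genes was -0.26, against -0.24 simulated, so nearly all of that covariance arises without any effect. Each gene counts equally in it, so it does not tell how many of the 1070 overlapping calls do.

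**Figure D3:**
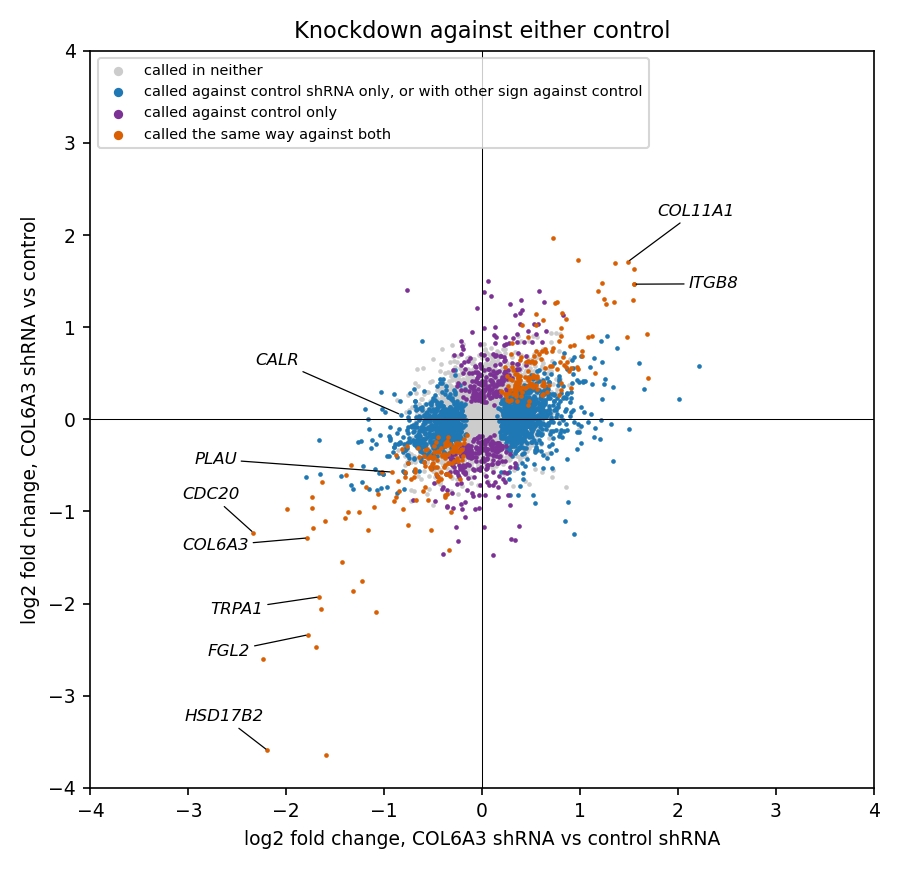
Log2 fold change of each gene for COL6A3 shRNA against control shRNA (x axis) and against control (y axis), for 10639 genes with a mean log2 CPM of at least 2, with 1 gene outside the axes. Coloured points are called genes as given in the legend, and COL11A1 lies at 1.49 and 1.71.

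**Figure D4:**
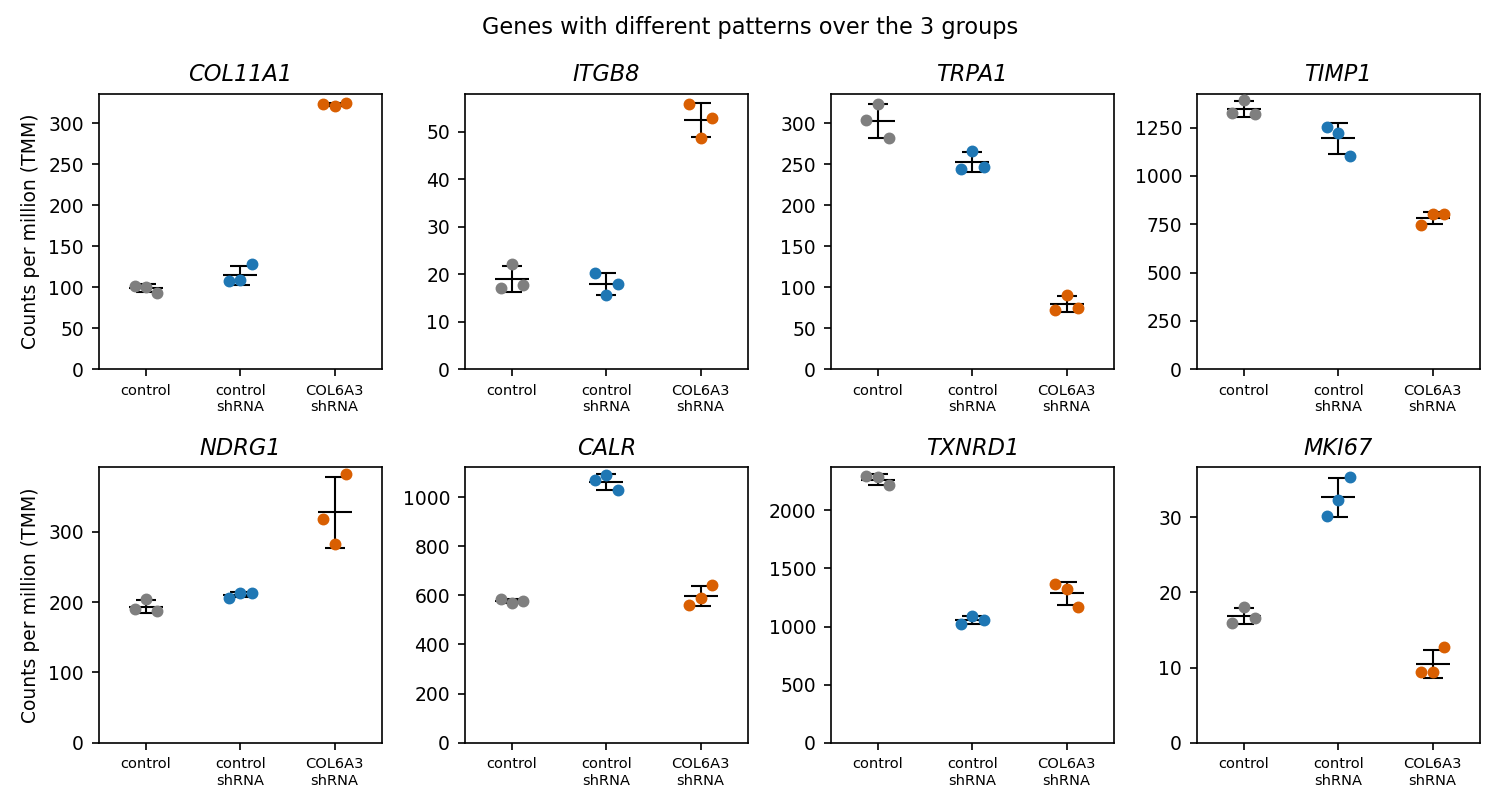
TMM-scaled CPM of 8 genes in each library, with points for libraries and bars for the mean ± SD (n = 3). TRPA1 averaged 79.6 CPM with the COL6A3 shRNA and 303 CPM in control, and CALR was highest with the control shRNA.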

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

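The fit with library quality weights and the fit without control shRNA replicates 2 and 3 were chosen after the data were seen. No refitted result reversed, and COL6A3 kept its direction and passed in each refit of single genes; it was not followed under glmTreat or the stricter adjusted p, where only genes were counted. On leaving out each library, its log2 fold change ranged from -1.84 to -1.75 against control shRNA, from -1.33 to -1.26 against control, and from 0.46 to 0.55 between the control groups. The changed genes ranged from 1203 to 2112 (COL6A3 shRNA against control shRNA), 1542 to 2522 (control shRNA against control), 517 to 981 (COL6A3 shRNA against control) and 194 to 302 (the same way against both controls). The lists called ranged from 18 to 20, 16 to 18 and 14 to 20. An adjusted p below 0.01 left 1017, 1282 and 443 genes, and 149 against both controls. Testing for at least 1.5-fold with glmTreat left 65 genes (29 up, 36 down), 72 (16 up, 56 down) and 58 (21 up, 37 down). An estimated correlation called 10, 11 and 9 lists. A higher correlation is not all that raised its p-values. For G2/M genes against control shRNA the estimate was -0.00045, below the preset 0.01, while the unadjusted camera p went from 3.9e-29 to 1.0e-05. For lung fibroblast markers against control shRNA the estimate was -0.010, while the camera adjusted p went from 0.0058 to 0.0508. A call lost with an estimated correlation therefore need not mean that the members of the list are correlated. What else raised the p-values was not tested. The fry test called 22, 17 and 21 lists. It lost the mitochondrially encoded and ribosomal lists against control shRNA (adjusted p = 0.146 and 0.264), and the mitochondrially encoded and respiratory chain lists between the control groups (adjusted p = 0.258 and 0.219). It gained TGF-beta targets between the control groups (adjusted p = 0.00572), and against control the DNA replication, YAP and SRF, epithelial and pericyte lists (adjusted p = 0.0413, 0.00831, 0.0464 and 0.00226). Quality weights called 1305 genes for COL6A3 shRNA against control, and the cause was not tested. This comparison, with 804 genes in the main fit, had 774, 981 and 952 without control shRNA replicate 1, 2 or 3. Those libraries are in neither of its groups and enter through the shared spread, filter and scaling. Fits of only the groups compared called 1103 genes for it, 1585 for COL6A3 shRNA against control shRNA and 1946 between the control groups. The fit over all groups thus set 1920 and 804 further apart. Leaving out control shRNA replicates 2 and 3, which leaves that group with 1 library assumed to vary like the others, called 1270 genes for COL6A3 shRNA against control shRNA. The other comparisons then had 1699 and 1192 genes. Of all counts of genes and lists under alternatives, 126 stayed within 1.5 times and 16 did not. Results were also counted for each named gene or list in each comparison under each alternative. For named genes 113 such results lost a call and 22 gained one, against 5584 without a change. For lists 66 lost and 40 gained a call, against 1803 without a change. The DESeq2 Wald test called 2243, 2597 and 1107 genes. The replicate block, with the replicate number as a term, called 1648, 2010 and 686 genes, 252 against both controls, and 19, 18 and 17 lists. Libraries with the same number did not deviate together (correlations from -0.16 to 0.028 over 9 pairs), and in 0 of 18 cases did a library correlate best with its own number, so the numbers are not taken to pair the libraries.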

Other observations

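In this part the tests of the adhesion and guidance genes, of a shift of the control shRNA group, of AL355075.4 and of amplification copies were chosen after the results were seen. The gene lists and their refits were planned. Counting other splits of the libraries was a set step, but the number of splits for both controls was raised after a first result. Genes of neuronal adhesion and axon guidance families (such as protocadherins, semaphorins, teneurins, FLRT and SLITRK genes) were picked by symbol after the largest rises had been read. Of 89 tested, 22 rose and 6 fell against control shRNA, and 19 rose and 3 fell against control. In both comparisons 15 rose and 1, SEMA3A, fell. NRXN3, a presynaptic adhesion protein, stood at 1.35 (SE 0.19) against control shRNA and 1.27 (SE 0.19) against control. MDGA1 stood at 1.12 (SE 0.11) and 0.90 (SE 0.11), and TENM4 at 0.55 (SE 0.13) and 1.02 (SE 0.13). The unadjusted camera p of this set was 0.00052 against control shRNA and 1.1e-06 against control, and p = 0.0712 and 0.024 with an estimated correlation. The set was read off these same data, so its p-values are not independent evidence.

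Further lists were not called by camera against control shRNA. For interferon-stimulated genes, 3 of 31 tested members rose and 28 did not pass (3 rose when adjusted over the list alone), with IFIT1 at 1.10 (SE 0.23). For TGF-beta targets, 5 of 24 tested members rose, 2 fell and 17 did not pass (8 rose and 3 fell when adjusted over the list alone). For contractile genes, 4 of 19 tested members fell, 3 rose and 12 did not pass (5 fell and 3 rose when adjusted over the list alone). For YAP and SRF targets, 5 of 24 tested members rose, 4 fell and 15 did not pass (5 rose and 4 fell when adjusted over the list alone). For lysosome and autophagy genes, 6 of 30 tested members rose, 0 fell and 24 did not pass (7 rose and 1 fell when adjusted over the list alone). For heat shock genes, 3 of 18 tested members fell, 1 rose and 14 did not pass (3 fell and 2 rose when adjusted over the list alone). For nuclear respiratory chain genes, 1 of 35 tested members fell and 34 did not pass (1 fell when adjusted over the list alone). With fry, which does not compare a list with other genes, the interferon, TGF-beta, YAP and SRF, and lysosome lists were called higher (adjusted p = 0.0320, 0.00120, 0.0284 and 0.0159), while the median of the YAP and SRF list was -0.013. With camera, the TGF-beta, lysosome and respiratory chain lists passed in some fits that left out 1 library. TGF-beta targets did so without control shRNA replicate 2 (adjusted p = 0.0417), control shRNA replicate 3 (0.0492), COL6A3 shRNA replicate 1 (0.0318), COL6A3 shRNA replicate 3 (0.0474) or control replicate 3 (0.0417). Lysosome genes did so without control shRNA replicate 2 (0.0158), COL6A3 shRNA replicate 2 (0.0211) or control replicate 3 (0.0417), and respiratory chain genes without control shRNA replicate 1 (0.0246), control shRNA replicate 3 (0.0204) or COL6A3 shRNA replicate 3 (0.0411).

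Markers of other cell types were few among the tested genes. Against control shRNA, edgeR called none of the 7 epithelial, 5 adipogenic, 4 keratinocyte and melanocyte, 3 mesothelial and neural, and 2 blood cell markers tested. At an unadjusted p below 0.05 these lists had 1, 2, 1, 0 and 0 genes. DESeq2 called 0, 1, 1, 0 and 0, and limma voom the same numbers. Adjusted over each list alone, 1 adipogenic and 1 keratinocyte and melanocyte marker rose. In the other comparisons edgeR, DESeq2 and limma voom called 0 epithelial, adipogenic or blood cell markers. At an unadjusted p below 0.05 there were 1, 1 and 0 of these between the control groups and 0, 1 and 1 against control. Against control they also called 0 of 4 keratinocyte and melanocyte markers, with 1 at an unadjusted p below 0.05. Among pericyte and muscle markers, 2 of 8 tested members rose and 6 did not pass (3 rose when adjusted over the list alone), and the list was not called by camera (adjusted p = 0.130, and 0.240 with an estimated correlation) but was by fry (adjusted p = 0.00068). Among endothelial markers, 1 of 6 tested members fell, 1 rose and 4 did not pass (1 fell and 1 rose when adjusted over the list alone). The endothelial list lost its call without control shRNA replicate 2 (adjusted p = 0.0691), COL6A3 shRNA replicate 1 (adjusted p = 0.0754), COL6A3 shRNA replicate 2 (adjusted p = 0.0640), control replicate 1 (adjusted p = 0.0545), control replicate 2 (adjusted p = 0.0582) or control replicate 3 (adjusted p = 0.0560). TEK, an endothelial receptor gene, stood at 68.6 ± 6.36 CPM in control and fell against both controls, at -1.22 (SE 0.12) and -1.76 (SE 0.12). In the metallothionein list, 1 of 4 tested members fell, 1 rose and 2 did not pass (3 fell and 1 rose when adjusted over the list alone). MT2A fell against both controls, at -0.88 (SE 0.088) and -0.39 (SE 0.087), the latter call being lost without control replicate 1 (adjusted p = 0.0639).

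Other splits of the libraries were set beside each count. In each of the 3 comparisons, 1 of the 10 splits of the 6 libraries, the real one, reached the real count. These counts were 1585, 1946 and 1103 genes in fits of those libraries alone, and the highest other split gave 0 each time, but 10 splits are too few for a share under 0.05. For lists the real splits gave 18, 18 and 16, and the other splits 4 to 12, 5 to 11 and 0 to 9, again among 10 splits. Camera with the preset correlation thus called lists in mixed splits where no gene was called. Its p-values may therefore be too small. Mixed splits can hold part of a group difference, and how many of their list calls are false was not tested. With an estimated correlation the real splits gave 7, 8 and 4 lists and the others 0. For genes changed the same way against both controls, 2 of 100 splits of the 9 libraries, the real one included, reached the real 291, a share under 0.05. Most other splits mixed libraries of different groups in the set compared. The share therefore shows only that libraries of a group resemble each other, and it cannot exclude chance differences between cultures. A first draw held 50 splits, of which 2 reached it, and the number was raised to 100 after that result had been seen, so the larger number was not fixed beforehand. The other split gave 555 genes, with the 3 control shRNA libraries together as the set compared, so it kept a real group whole. The next highest gave 2.

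The control shRNA group departed from both other groups for many genes, and a shift of that group is a candidate explanation for part of the calls against it. Against control the median log2 fold change was -0.051 for the unfolded protein response and 0.036 for ATF4 genes, as such a shift would give. The first list was nevertheless called lower against control without COL6A3 shRNA replicate 3 (adjusted p = 0.0319). For cholesterol synthesis the median against control was -0.14 with the COL6A3 shRNA and -0.53 with the control shRNA. With the COL6A3 shRNA this list was called lower by camera with the preset correlation (adjusted p = 1.3e-05), but not with an estimated one (adjusted p = 0.155). A shift of the control shRNA group alone may thus not describe it. That such a shift accounts for all of the fall in G2/M genes (median -0.50 against control) or in proteases and inhibitors (median -0.19) is argued against, since both lists were called the same way against control with both correlations. Fewer independent fragments in control shRNA replicates 2 and 3 are argued against as the whole cause, because 54.8% of the 1920 genes stayed called with the same sign without both libraries, in a fit with fewer libraries. An effect of the knockdown, of the control hairpin, of transduction or of culture on these genes stays open, as does an effect of the COL6A3 shRNA on other transcripts, since the labels name 1 particle product for each.

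Reads of AL355075.4 (ENSG00000259001, chromosome 14, 20343048 to 20343685, minus strand, GRCh38) may come from the lentiviral construct. It had 0 counts in control. Over a floor of 3 counts per library, its level was 1141-fold higher with the control shRNA and 752-fold higher with the COL6A3 shRNA. That floor takes reads as independent, but control libraries held an estimated 5.27 to 7.03 counts per independent fragment. These folds are therefore not lower bounds. AL355075.4 was the 1 gene in the table with 0 counts in control and at least 20 in every shRNA library. It spans RPPH1 (20343075 to 20343407), which had 0 counts and next to which lies the H1 promoter of many hairpin vectors, but the promoter of these particles is not given in the sources used here. Its 10 tested neighbours within 200 kb had a median absolute log2 fold change of 0.171 between control shRNA and control, and 2 of them were called, which argues against a change of the whole region. A response of this gene alone to transduction stays open.

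Replicates varied more than independent reads would, and amplification copies of the same fragments are a candidate explanation. The ratio of variance over mean at mean counts of 80 to 320 to that at 5 to 20 was at most 1.19 over the 3 groups, where biological variation of a constant share would raise it with the mean, although at 1280 to 5120 counts variance over mean reached 12.1 to 20.2 from 7.28 to 11.7 at 5 to 20. From genes expected at 5 to 40 counts but found at 0, counts per independent fragment were estimated at 5.12 to 7.03 in 7 libraries and at 10.6 and 9.69 in control shRNA replicates 2 and 3, taking genes to vary little between libraries. Those libraries had quality weights of 0.624 and 0.626. No biological explanation was tested for this pattern.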
